A study of Mus musculus with 10 samples.

How the data were processed

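The libraries were made from genomic DNA of mouse embryonic stem cells and from the plasmid pool of the mouse GeCKO v2 library, part A, per the labels' protocols. Cells were transduced at a multiplicity of infection of 0.3 and selected with puromycin at 0.5 µg/mL. Before sorting they received biliverdin at 25 µM, the chromophore that iRFP needs. At least 1.75 (in units of 1e5) cells were taken at each of the 4 sorts, and 200000 cells were collected for DNA, per the labels, which is 3.03 cells for each guide of the library. The labels also state a PCR input worth approximately 2000 cells per guide, and which of these holds for which library is not clear. Guides were amplified in 48 parallel reactions of 22 cycles. The deposited counts are whole reads per guide with no normalization, made by the authors with cutadapt (version not given in the sources used here) and MAGeCK 0.5.5, per the submitters' processing notes. The mismatch setting is not given in the sources used here. The table holds 1 sorted column for the 2 technical replicates of each line, and whether they were added or 1 was chosen is not given, so technical replicates were not compared here. The sorted columns also carry the word Low, whose meaning the labels do not state. A further 2 per-sample columns with no sample in the labels were not used.

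The table lists 65959 guides, of which 1000 are non-targeting, under 21486 gene and miRNA names, 1132 of them miRNAs. Of these names 19041 were found as symbols and 2220 as synonyms in a RefSeq gene table of the assembly GRCm38.p6, and 87 names other than miRNAs were not found. Names are printed as in the deposited files. No genome was used here, so guide positions and exons are not given. Guides of near-identical gene copies, such as olfactory and vomeronasal receptors, can cut more than 1 gene and are uncertain at the level of the single gene.

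The main tests were edgeR 4.0.16 quasi-likelihood fits per guide with TMM factors (glmQLFit and glmQLFTest, Benjamini-Hochberg, two-sided), run in R 4.3.3. Sorted against unsorted used 3 sorted and 3 unsorted libraries with the cell line as a block, because each sorted population came from the same transduced line as its unsorted one, and guides kept by filterByExpr at a minimum count of 10. Unsorted against plasmid used the 3 unsorted libraries and the plasmid library, which was assumed to vary like them, and guides with at least 30 plasmid reads. Genes with at least 2 guides were tested with fry and 29 gene lists with camera at a preset correlation of 0.01, both from limma 3.58.1. The gene value is the mean over guides of the fitted log2 ratio, which follows the line with most reads. The value per line is the log2 ratio of normalized CPM with a prior count of 2, so the fitted value can lie outside the range of the lines. TMM factors ran from 0.241 to 4.45 in the sorted comparison, so levels relative to other guides depend strongly on the scaling. The lists, the tests and the alternatives were fixed before the data were examined. So was the rule for named genes: the 12 genes with the smallest fry p in each direction among those with the same sign in all 3 lines, the 4 highest and 4 lowest per line among genes with 3 or more measured guides all over 2-fold on one side, the reporter genes, Trp53 and the 2 highest and 2 lowest members of each list. Fewer genes are named where fewer met the rule, and not every gene or list member that met it is named.

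Other tests were added after the counts had been seen, because few guides had reads in all lines. A guide was called present at 10 reads or more and at no less than 0.005 of its highest count in another cell library, a limit meant to remove reads carried over between libraries. The edgeR, fry and camera fits, the counts within each line and the correlations between lines set no such limit. Expanded genes were found by summing, over 3 lines, the guides at 100 CPM or more and 10 times the plasmid CPM. The exact probability of that sum came from the guides in the same of 10 equal strata of plasmid count, with Benjamini-Hochberg adjustment, one-sided. Gains after sorting used 100 CPM and 4 times the unsorted CPM, in strata of unsorted presence. Retention of a list was compared, two-sided, with 10000 random guide sets of the same plasmid strata. Floors use 3 counts. Wilson intervals are at 95%.

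Alternatives were DESeq2 1.42.0, its size factors, total counts, scaling on non-targeting guides, other count minimums, no replicate block, counts summed per gene, camera with an estimated correlation, fry on the lists, and each line left out. The tests were tested on simulated data. On counts simulated for 1736 guides at a dispersion of 0.1, edgeR recovered 90% of 200 guides changed 4-fold and 100% of those changed 16-fold. At the dispersion of the data, 2.9, it recovered 0% of those changed 16-fold. The expansion test recovered 13 of 20 simulated genes whose guides expanded with probability 0.5, 0 of 20 at 0.2, and made 0 false calls among 20686 genes. The retention test passed 4 of 100 unchanged lists at an unadjusted p under 0.05 and 100 of 100 lists that had lost 0.5 of their retained guides. Figures were drawn with matplotlib 3.10.9, and other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.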

Results

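Mouse embryonic stem cells carrying GFP on one allele and the near-infrared protein iRFP on the other allele of Nanog, Trim28 or Dnmt3l were transduced with a pooled CRISPR knockout library, and the guides integrated in the genome were counted by sequencing. Nanog is a transcription factor of naive pluripotency, Trim28 a co-repressor that silences transposable elements, and Dnmt3l a cofactor of de novo DNA methylation. Cells in which the GFP to iRFP ratio lay near 1 were collected in 4 rounds of sorting, with growth in between, while a parallel culture was passaged without sorting. According to its title, the study searched for genes that set the kinetics of transcriptional bursting, which make the alleles of a gene differ in output within a cell. The labels describe 10 samples: 1 unsorted library and 2 technical replicates of the sorted library for each of the 3 lines, and 1 library of the plasmid pool. The count table held 1 sorted column per line, so 7 libraries were compared, and the line was the replicate (n = 3). Nothing in the labels says that lines were transduced more than once, so the spread between lines includes both the lines and their separate transductions.

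Total counts were 10592777 for the plasmid pool, 6709289, 8305843 and 8442566 for the unsorted Nanog, Trim28 and Dnmt3L lines, and 13851748, 14080238 and 15855525 for their sorted populations. Of the 65959 guides, 0.75% (95% Wilson interval 0.687 to 0.819) had no read in the plasmid pool. The same share was 76.2% (75.8 to 76.5), 87.6% (87.4 to 87.9) and 81.7% (81.4 to 82.0) in the unsorted Nanog, Trim28 and Dnmt3L lines, and 89.6% (89.4 to 89.9), 90.9% (90.7 to 91.1) and 90.5% (90.3 to 90.8) after sorting. The 100 most abundant guides held 1.55% of the plasmid reads (1.54 to 1.55). They held 80.4% (80.4 to 80.5), 59.1% (59.1 to 59.1) and 43.6% (43.6 to 43.6) of the unsorted Nanog, Trim28 and Dnmt3L libraries and 89.9% (89.9 to 89.9), 82.1% (82.1 to 82.2) and 84.4% (84.4 to 84.4) of the sorted ones. These intervals, and the limit of 3 reads used below where a count was 0, cover counting error only, since amplified reads are not independent molecules.

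**Figure D1:**
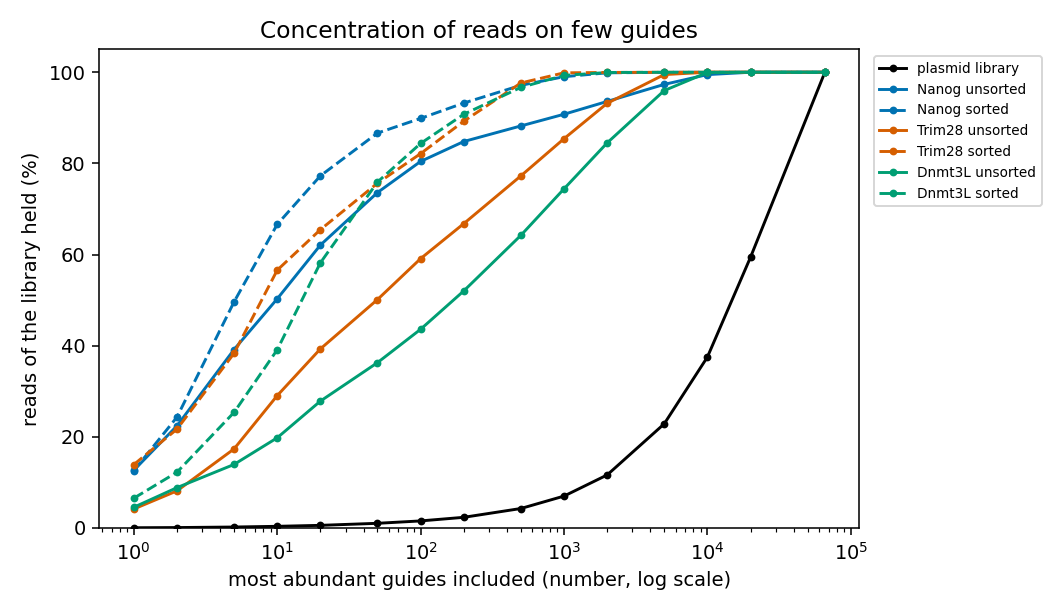
Percent of each library's reads (y axis) held by its most abundant guides (x axis, number of guides on a log scale), with solid lines for the plasmid pool and unsorted cells and dashed lines for sorted cells. The 100 most abundant guides held 1.55% of the plasmid reads and between 43.6% and 89.9% of the reads of the cell libraries.

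Of the reporter genes, Nanog alone had no guide read in any cell library. The 3 Nanog guides had 332, 116 and 30 reads in the plasmid pool and 0 reads in all 6 cell libraries. Against the floor of 3 reads per library, their summed abundance was at least 101-fold, 125-fold and 127-fold lower in the unsorted Nanog, Trim28 and Dnmt3L lines than in the pool. Of the Trim28 guides, with 478 plasmid reads together, 1 (ATAATTCTCCACGATGTCTT) had 719 reads in the unsorted Trim28 line and 2 reads after sorting, and no other read of a Trim28 guide was found in any cell library. Dnmt3l guides had 365 plasmid reads together and 318, 894 and 15 reads in the unsorted Nanog, Trim28 and Dnmt3L lines, against 0, 3 and 1 after sorting. Nanog was called lower in unsorted cells (edgeR and fry, adjusted p = 0.0132), but not without the Trim28 line (0.189), without the Dnmt3L line (0.163) or on counts summed per gene (0.462), while Trim28 (adjusted p = 0.130) and Dnmt3l (adjusted p = 0.7) were not called. The Nanog result has to be read beside 231 of 1093 olfactory receptor genes that likewise had no read in any unsorted library.

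Unsorted cells were compared with the plasmid pool to find guides that rose or fell apart from the sort. No sample separates loss in culture from guides not carried past transduction, and even non-targeting guides were present in only 18.8% of cases. The gains called in every setting of an expansion test chosen after the counts had been seen, though not by fry with TMM, were in guides against Trp53, which encodes the tumour suppressor p53, Ptpn2, a tyrosine phosphatase that restrains JAK-STAT signalling, and Lamtor1, a subunit of the lysosomal Ragulator complex. Guides against Lamtor4, also of Ragulator, Rraga, which encodes the GTPase RagA, Flcn, which encodes folliculin, its partner Fnip1, and Fbxw7 passed the same test but not in every setting. Summed over the guides of a gene, the log2 ratio of unsorted CPM to plasmid CPM was 7.55 ± 1.79 for Trp53, 7.79 ± 0.78 for Ptpn2, 7.89 ± 1.19 for Lamtor1, 8.08 ± 1.44 for Flcn and 5.41 ± 1.48 for Fnip1 (SD, n = 3 lines). Each was above 0 in all 3 lines. The choice of these genes fixed that sign, since each had a guide at 100 CPM or more in every unsorted line. Guides against the ribosome, spliceosome and replication machinery were lost more often than other guides of like plasmid abundance.

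A gene counted as expanded when more of its guides than chance allows, over the 3 lines, reached 100 CPM and 10 times their plasmid CPM in unsorted cells. This exact randomization test was chosen after the counts had been seen. Of 20686 genes with at least 2 guides, 8 passed an adjusted p of 0.05 and 168 had an unadjusted p under 0.05. They were Trp53 (adjusted p = 2.18e-05), Lamtor1 (4.57e-05), Ptpn2 (0.00048), Fnip1 (0.00133), Lamtor4 (0.00362), Flcn (0.0231), Fbxw7 (0.0303), which encodes a substrate receptor of a ubiquitin ligase, and Rraga (0.0395). Trp53 had 3, 1 and 3 expanded guides in the Nanog, Trim28 and Dnmt3L lines, Lamtor1 had 3, 2 and 2, and Ptpn2 had 2, 2 and 2. Fbxw7 had 2, 0 and 2, and Rraga 0, 1 and 3, so each had no expanded guide in 1 line. Their mean log2 ratios were 5.65 ± 5.91 for Fbxw7 and 5.24 ± 4.23 for Rraga (SD, n = 3), with the spread between lines as large as the mean or nearly so. Lamtor4 reached 6.04 ± 2.83. Rraga was not called at 30 CPM or at 300 CPM in place of 100, which left 7 genes each. Lamtor4, Fbxw7 and Rraga were not called when a guide had to reach 0.02, in place of 0.005, of its highest count in another cell library, or when the Dnmt3L line was left out, which left 5 genes in both cases. Without the Nanog line 6 of the 8 remained, with Flcn and Fbxw7 lost. Without the Trim28 line 5 of the 8 remained, with Flcn, Fnip1 and Rraga lost, and Bri3 was added (named after its value was seen).

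Single guides show the scale of these gains. The Trp53 guide AACAGATCGTCCATGCAGTG had 259 reads in the plasmid pool and 178046, 20436 and 14908 reads in the unsorted Nanog, Trim28 and Dnmt3L lines. The Ptpn2 guide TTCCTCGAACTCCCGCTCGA had 410 plasmid reads and 55518, 218343 and 175 reads, whereas the Ptpn2 guide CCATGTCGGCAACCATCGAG had 225 plasmid reads and 11757, 7583 and 83390. Summed over their guides, Trp53 stood 653-fold, 54.7-fold and 183-fold above the pool in the Nanog, Trim28 and Dnmt3L lines, Ptpn2 152-fold, 412-fold and 175-fold, Lamtor1 120-fold, 595-fold and 189-fold, and Flcn 94.5-fold, 688-fold and 305-fold. Large gains were not confined to these genes. In the unsorted Nanog, Trim28 and Dnmt3L lines, 223, 612 and 757 guides met the expansion threshold. A non-targeting guide had 225 reads in the plasmid pool and 134138 in the unsorted Trim28 line. The size of a gain alone therefore does not show an effect of the gene.

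**Figure D2:**
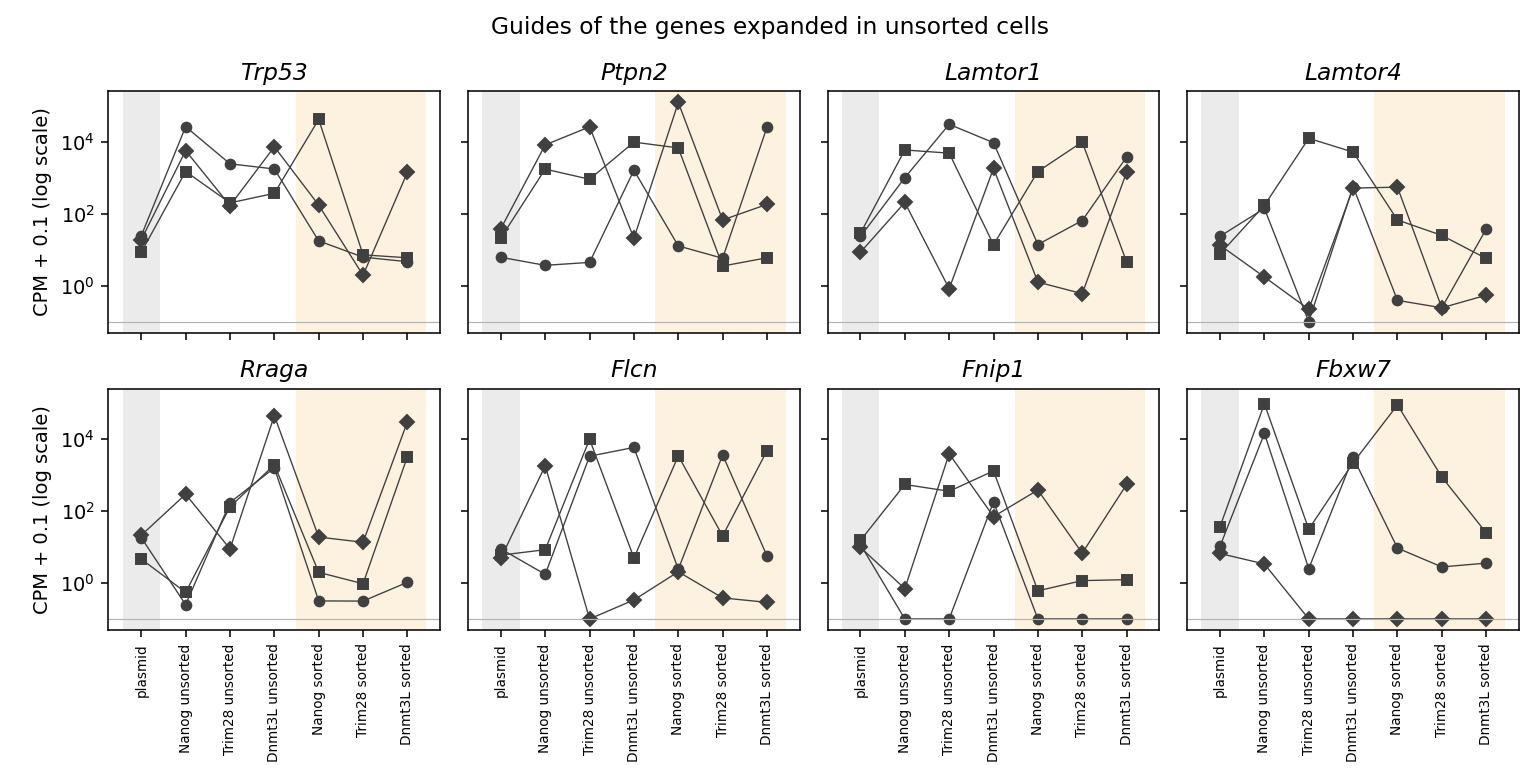
CPM plus a pseudocount of 0.1 (y axis, log scale) of each guide of the 8 expanded genes (1 line with its own marker per guide) in the plasmid pool (grey band), the unsorted lines and the sorted populations (shaded, right). Trp53, Lamtor1 and Ptpn2 had expanded guides in all 3 unsorted lines, while the Rraga guide above 100 CPM in the unsorted Nanog line did not count, since it stayed under the carry-over limit.

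Some list members passed the expansion test when it was adjusted over their list alone. Adjusted over the list alone, 5 PI3K-AKT-mTOR activators passed (Lamtor1, Lamtor2, Lamtor4, Lamtor5 and Rraga), against 3 over all genes. In the list of genes acting in the exit from naive pluripotency 3 passed (Axin1, Flcn and Fnip1), against 2 over all genes. Of the p53 pathway 1 (Trp53) passed both ways. The members of the mTOR activator list that passed encode Ragulator subunits and RagA, which bring mTORC1 to the lysosome, not PI3K or AKT.

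Loss was measured as the share of a list's guides found in unsorted cells, averaged over the 3 lines, and set against 10000 random sets of guides matched on plasmid count (a randomization test chosen after the counts had been seen). It passed an adjusted p of 0.05 in 10 of 29 lists. Ribosomal protein guides were found in 6.73% of cases against 15.6% by chance, and all guides of 42 of the 76 genes had no read in any unsorted library. The corresponding values were 6.82% against 15.5% and 17 of 34 genes for the proteasome, 5.61% against 14.4% and 20 of 37 for the spliceosome, and 7.92% against 17.2% and 17 of 43 for DNA replication. The adjusted p of these 4 lists was 0.00116, from the smallest p that 10000 random sets can give (0.0002). Retention was also lower for tRNA synthetases (7.41% against 15.4%, adjusted p = 0.00709), RNA polymerase II and general factors (9.17% against 15.1%, adjusted p = 0.00709), Mediator (9.12% against 15.4%, adjusted p = 0.00663) and pausing and elongation factors (9.43% against 15.6%, adjusted p = 0.0087). None of these last 4 lists kept its call with every line left out: the adjusted p was 0.0883 without Nanog and 0.116 without Trim28 for tRNA synthetases, 0.0992 without Nanog and 0.0644 without Dnmt3L for Mediator, 0.116 without Trim28 and 0.114 without Dnmt3L for pausing and elongation, and 0.0644 without Dnmt3L for RNA polymerase II. The mean gap to chance was −8.85 ± 1.80 percentage points for ribosomal proteins, −8.80 ± 0.75 for the spliceosome and −9.23 ± 1.66 for DNA replication (SD, n = 3). Proteasome guides differed more between lines (−8.68 ± 8.65), with −17.8 in the Nanog and −0.652 in the Trim28 line, and without the Nanog line their adjusted p was 0.266.

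Guides of PI3K-AKT-mTOR activators were found more often than chance (25.5% against 16.3%, gap 9.16 ± 1.43 percentage points, adjusted p = 0.00116), as were guides of the naive exit list (27.8% against 16.8%, gap 10.9 ± 9.38, adjusted p = 0.00387). Neither list passed when the guides of the expanded genes were left out (adjusted p = 0.227 and 0.162), and the naive exit list did not pass without the Trim28 line (adjusted p = 0.348). Other lists that did not pass include olfactory receptors (15.5% against 15.5%, adjusted p = 0.989) and vomeronasal receptors (14.5% against 16.2%, adjusted p = 0.068), which serve as genes not used by these cells. Pluripotency transcription factors were found in 12% of cases against 15.2% (adjusted p = 0.439), LIF-STAT3 in 9.52% against 16.1% (adjusted p = 0.325), Polycomb in 16.3% against 16.6% (adjusted p = 1), DNA methylation and TRIM28 silencing in 12.3% against 15.8% (adjusted p = 0.325), and TGF-beta, NODAL and BMP in 10.5% against 15.0% (adjusted p = 0.162). The p53 pathway (21.6% against 17.2%) and the p53 antagonists (3.33% against 13.6%) had adjusted p of 0.386 and 0.269. Non-targeting guides were found in 18.8% of cases against 14.5% for guides of like plasmid count, 4.28 ± 1.31 percentage points more (SD, n = 3, permutation p = 0.0002, the smallest possible).

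**Figure D3:**
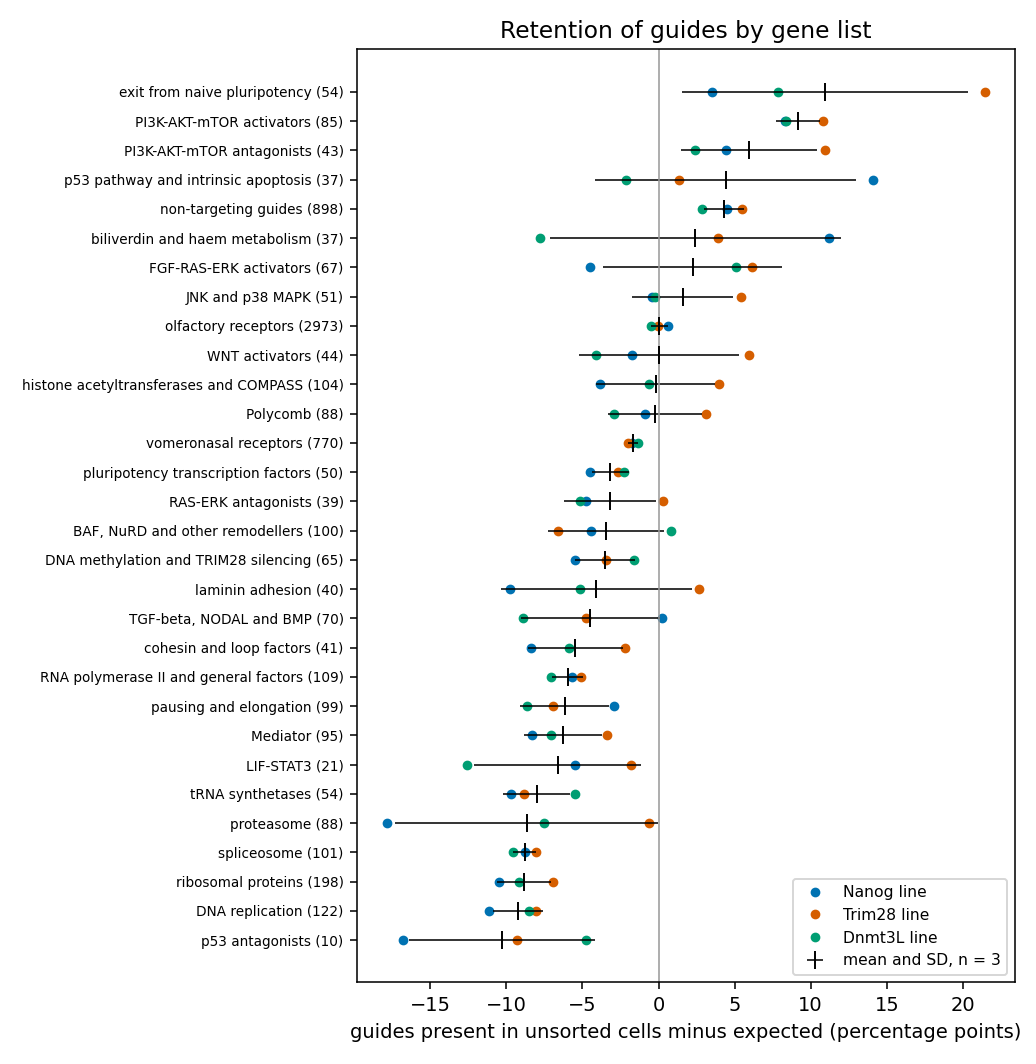
Guides present in unsorted cells minus the number expected from guides of like plasmid count, in percentage points (x axis), for each gene list and the non-targeting guides (y axis, number of guides in brackets). Coloured points are the 3 lines, and the black tick and bar are their mean and SD; ribosomal protein, spliceosome and DNA replication guides lay below 0 in all 3 lines, and mTOR activator guides above 0.

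The planned tests of unsorted cells against the pool gave a coarser picture. For 59001 guides with at least 30 plasmid reads, edgeR called 0 guides (5212 lower and 0 higher at an unadjusted p under 0.05, smallest adjusted p = 0.235), and DESeq2 called 0 (129 at an unadjusted p under 0.05). The median guide log2 ratio, set by guides without reads, was −7.67 with TMM, −7.15 with the size factors of DESeq2, −8.37 with total counts and −7.49 when scaled on non-targeting guides, and serves only to show the shift between scalings. Over the guides of each gene, fry called 5365 of 20686 genes lower and 0 higher (2 higher at an unadjusted p under 0.05), and 1 higher with total counts or with scaling on non-targeting guides, which was Lamtor1 in both. Of 299 sets of 3 non-targeting guides, 49 (16.4%) were also called lower, against 25.9% of genes. The gene count was 0 without the Trim28 or the Dnmt3L line, 9107 without the Nanog line and 0 on counts summed per gene. By list, the genes called lower were 39 of 71 tested for ribosomal proteins (41 adjusted over the list alone), 18 of 34 for the proteasome (20), 19 of 36 for the spliceosome (19), 19 of 43 for DNA replication (21), 9 of 19 for tRNA synthetases (10), 17 of 39 for RNA polymerase II and general factors (17), 12 of 33 for Mediator (12) and 16 of 36 for pausing and elongation (18). They were 261 of 1067 for olfactory receptors (261 adjusted over the list alone), 6 of 18 for pluripotency factors (7), 3 of 7 for LIF-STAT3 (3), 3 of 29 for mTOR activators (3) and 2 of 19 for the naive exit list (2). Lost members include Rpl17 (713 plasmid reads) and Rps2 (500) of the ribosome, Psmd5 (826) of the proteasome, Xab2 (1148) and Eftud2 (459) of the spliceosome, Orc1 (782) and Orc5 (761) of the replication origin complex, Jak1 (553) and Lif (429) of LIF signalling, and Dnmt1 (500) and Setdb1 (570) of DNA methylation and H3K9 silencing. Each of them had 0 reads in all 3 unsorted libraries and an adjusted p of 0.0132 with fry. The same held for the receptor genes Olfr466 (1042 plasmid reads) and Vmn2r87 (1164), and for Apaf1 (623) and Cdkn1a (460) of the p53 pathway list. For a single gene, such a loss therefore does not show a need for that gene. Other members kept reads and were not called: in the unsorted Nanog, Trim28 and Dnmt3L lines Rps6 had 0, 1018 and 203, Rpl35 0, 105 and 4393, Psmb1 0, 53 and 326, Snrpc 47, 1 and 1384, Mcm4 10, 0 and 1584, Il6st 0, 146 and 993, and Dnmt3a 64, 0 and 1854.

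The genes with the smallest fry p among those with a ratio of the same sign in every line were Mapk6, Gm4177, Pde4dip, Pax1, Txndc9, Trpv2, Vmn2r85, Olfr849, Prss32, Asxl2, Bai1 and Furin, all lower (adjusted p = 0.0132). The fitted log2 ratio of unsorted over plasmid was −5.46 for Mapk6, with −3.24, −2.71 and −2.73 in the Nanog, Trim28 and Dnmt3L lines, and −6.19 for Gm4177, with −6.24, −6.01 and −5.96. For Asxl2 it was −0.51, against −3.10, −3.83 and −2.36 in the lines, because the fitted value follows the line with most reads. Summed over its guides, Asxl2 had 94.4 CPM in the unsorted Dnmt3L line against 49.6 in the pool, so it was not lower there. In the other direction the rule gave Ptpn2, Lamtor1, Flcn, Trp53, Nmt1, Lamtor4, Fnip1, Rraga, Hk2, Lamtor2 and Frs2, none of which passed fry with TMM, while Lamtor1 passed with total counts (adjusted p = 0.000303) and with scaling on non-targeting guides (0.0117). With TMM the smallest adjusted p was 0.0804 for Ptpn2 (fitted log2 ratio 8.51, with 6.53, 5.66 and 6.12 in the lines), followed by 0.0924 for Lamtor1 (8.72, with 8.00, 5.73 and 5.92). Trp53 had an adjusted p of 0.262 (9.44, with 10.68, 5.66 and 7.52).

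Against all other guides, camera called the ribosomal protein (adjusted p = 0.0019), spliceosome (0.0182), proteasome (0.0244), DNA replication (0.028) and RNA polymerase II (0.0407) lists lower, and the naive exit (0.00179), mTOR activator (0.0244) and mTOR antagonist (0.028) lists higher. With an estimated correlation each of the 8 had an adjusted p of 0.993, and none was called. Leaving out any 1 line left 4 lists.

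Cells sorted for a GFP to iRFP ratio near 1 were dominated by a few guides that differed between the 3 lines, some of them already leading before the sort, and no guide, gene or list passed the edgeR, fry and camera tests with the line as a block. Of the guides present after sorting, 36.6%, 34.7% and 44.7% were also present in the unsorted cells of the Nanog, Trim28 and Dnmt3L lines, which is 829, 365 and 781 guides where 541, 151 and 371 would be shared by chance among guides of like plasmid count. Guides present before the sort held 64.8% (95% Wilson interval 64.8 to 64.9), 73.4% (73.4 to 73.5) and 74.3% (74.3 to 74.3) of the sorted reads. A guide was treated as absent before the sort when its unsorted count lay under the carry-over limit set by its sorted count. In the Nanog line this held for leading guides against Sema3f (479 reads unsorted, 741954 sorted), Pfkl (1151, 734480) and Nmt1 (384, 639371). The rule thus lowers these shares by leaving out guides that rose most. Whether the unsorted reads of such guides were carried over was not tested. Trp53 guides had a fitted log2 ratio of sorted over unsorted of −3.40, with −2.66, −3.15 and −3.42 in the lines (adjusted p = 0.359). With the size factors of DESeq2 it was −0.47, with total counts −6.41 and on counts summed per gene −0.18. The mean over guides also hides the Trp53 guide AGTGAAGCCCTCCGAGTGTC, which had 10080 reads in the unsorted and 586635 in the sorted Nanog line. Pfkl, which encodes a phosphofructokinase subunit, and mmu-mir-182 lay highest among genes whose mean over tested guides had one sign in every line, at 0.88 (adjusted p = 0.390) and 3.65 (adjusted p = 0.615). Their summed reads were not higher in every line, with 102 after sorting against 290 before for Pfkl in the Trim28 line and 186 against 307 for mmu-mir-182 in the Dnmt3L line.

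In the paired edgeR fit, with the line as a block, 0 of 1736 guides were called (143 lower and 0 higher at an unadjusted p under 0.05, smallest adjusted p = 0.485), and 0 of 66 genes (6 lower at an unadjusted p under 0.05, smallest adjusted p = 0.359). DESeq2 called 623 of the same guides, 367 higher and 256 lower, and 812 had an unadjusted p under 0.05. The coefficient of variation between lines was 170%. On counts simulated with this spread and no change, DESeq2 called 68 of 1736 guides and edgeR 0, and of 200 guides changed 256-fold edgeR recovered 1%. DESeq2 recovered 137 of these 200 and called 102 unchanged guides. A count of 0 from edgeR at this spread therefore does not show that guides kept their abundance. The median guide log2 ratio was −2.0 with TMM, 0.49 with the size factors of DESeq2, −3.80 with total counts and −1.61 when scaled on non-targeting guides, so the direction of a typical guide depends on the scaling. Without the line as a block 73 guides were called lower, and without the Nanog line 1 gene was called lower (Gli2, named after its value was seen).

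**Figure D4:**
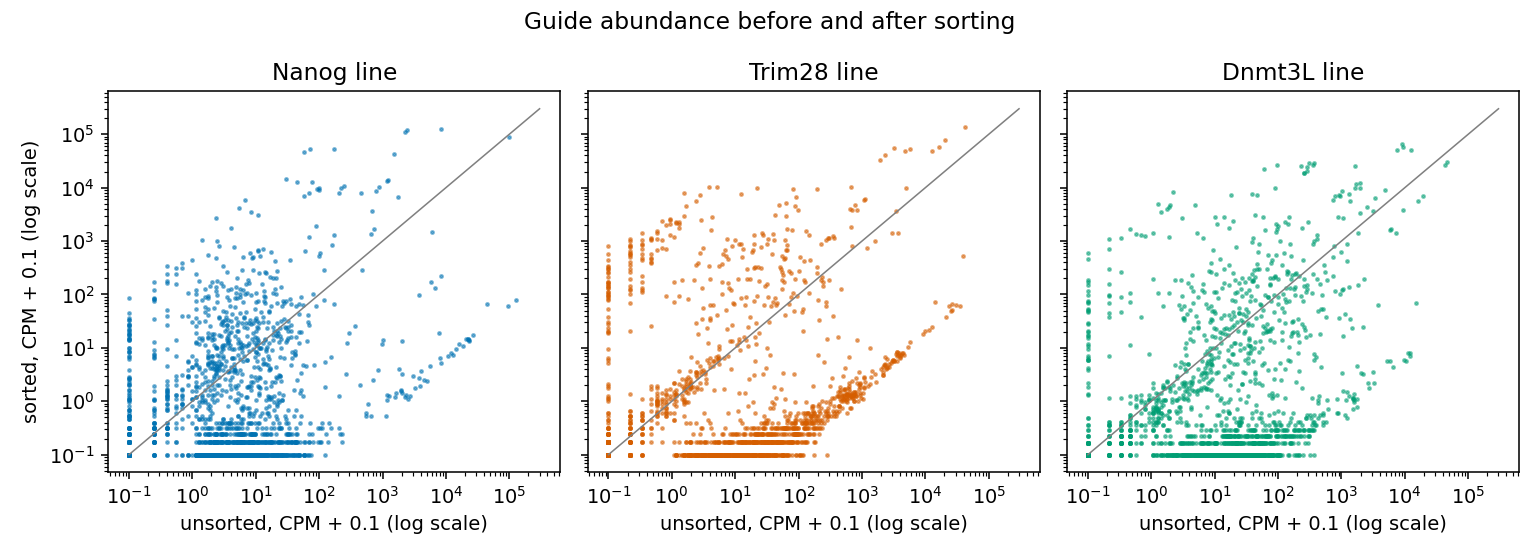
CPM plus a pseudocount of 0.1 after sorting (y axis, log scale) against the same in unsorted cells (x axis, log scale) for the 1736 tested guides (1 point each) in the 3 lines, with a grey line where both are equal. Guides lay far on both sides of the grey line in every line.

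The genes with the smallest p among those whose mean over tested guides had one sign in every line had mostly lower means after sorting: 2310061N02Rik (fitted log2 ratio −7.12), Olfr1157 (−3.55), Dlg2 (−5.01) and Trp53 (−3.40), each with an adjusted p of 0.359, mmu-let-7f-2 (−3.97) and Olfr996 (−1.95) at 0.386, and Fpr-rs3, Myo6, Ndufaf2, Frs2, Dpy19l3 and mmu-mir-7032 at 0.390. Their summed reads were not lower in every line: after sorting Frs2 had 16306 reads against 847, mmu-mir-7032 5627 against 82 and Olfr996 1033 against 240 in the Nanog line, and Dlg2 4360 against 733 and mmu-let-7f-2 1118 against 486 in the Dnmt3L line. With the size factors of DESeq2 the log2 ratio of Olfr996 was 1.03, and with total counts that of Pfkl was −1.61. Of the 29 lists, 17 had at least 2 measured guides and 0 were called by camera (smallest adjusted p = 0.823), by camera with an estimated correlation (adjusted p = 0.958) or by fry (smallest adjusted p = 0.0964). Over all genes 0 list members were called. Adjusted over the list alone 1 was, Trp53 in the p53 list (adjusted p = 0.0218), where it was the single gene tested.

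A gain was also sought by the exact randomization test, with a guide counted when it reached 100 CPM and 4 times its unsorted CPM after sorting. It called 0 of 20686 genes (353 at an unadjusted p under 0.05, smallest adjusted p = 0.640, for Gria3), and 0 under every alternative threshold and with any line left out. Adjusted over the list alone 1 gene passed, Hmox2 in the biliverdin and haem list (adjusted p = 0.0146).

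Within each line there was 1 library per state and hence no replicate check. In the Nanog line 61 of 2232 genes with at least 2 measured guides had all of them over 2-fold up after sorting and 1497 all of them over 2-fold down, against a mean of 50.4 (38 to 67) and 1487 (1444 to 1528) in 100 shuffles of guides among genes. The numbers were 16 up and 492 down of 730 in the Trim28 line, against 15.6 (8 to 27) and 509 (484 to 538). In the Dnmt3L line they were 35 up and 1113 down of 1613, against 29.2 (18 to 39) and 1117 (1074 to 1159). All 6 counts lay within the range of the shuffles. Ptpn2 was the 1 gene with 3 measured guides all up, in the Nanog line (mean log2 ratio 3.49). Of these 3, 1 guide rose only from 24 to 175 reads there, and had 411063 reads in the sorted Dnmt3L library. Its 175 reads lay under the carry-over limit used elsewhere, which these counts do not set. Carried-over reads are therefore not excluded for that guide. Among the lowest in that line were Gzmk (−7.13), Wdr59 (−7.03) and Ptcd2 (−6.85). The lowest were Tlr7 (−5.99), Dnaic1 (−5.37), Rab3il1 (−5.24) and mmu-mir-1963 (−5.06) in the Trim28 line, and Zfp473 (−8.02), Cldn13 (−7.74), Wdfy3 (−7.42) and Syn1 (−7.37) in the Dnmt3L line.

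The leading guides of the sorted libraries are named after their counts were seen. In the Nanog line the Ptpn2 guide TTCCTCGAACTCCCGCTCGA held 12.6% of the sorted reads (95% Wilson interval 12.6 to 12.6; 1741285 reads, against 55518 unsorted), ahead of guides against Krtap4-16 (11.8%, 11.7 to 11.8), Chodl (10.9%, 10.9 to 10.9) and Fbxw7 (9.0%, 8.99 to 9.02; 653782 reads unsorted, at rank 2). In the Trim28 line a guide against Tcf7l1, a repressor that acts in WNT signalling, held 13.9% (13.9 to 13.9, with 1959004 reads against 346097 unsorted, at rank 1). It was followed by a guide against Cln6 (7.77%, 7.76 to 7.78) and a non-targeting guide (5.85%, 5.84 to 5.86). In the Dnmt3L line Scn1a (6.53%, 6.52 to 6.54), Ostf1 (5.70%, 5.69 to 5.71), Pi16 (5.10%, 5.09 to 5.11) and Nmt1 (4.96%, 4.95 to 4.97) led, and the Rraga guide that ranked 1 before the sort ranked 5 after it (3.06%, 3.05 to 3.07). Except for Ptpn2 and Rraga, no other guide of these genes was present at 100 CPM or more in the same sorted library. Each of those leads therefore rests on 1 guide and does not show an effect of the gene.

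Gene mean log2 ratios of sorted over unsorted showed little correlation between lines. Across the 66 genes tested, Pearson's r was −0.004 for Nanog and Trim28 (Spearman's rho 0.009), 0.093 for Nanog and Dnmt3L (0.099) and 0.017 for Trim28 and Dnmt3L (0.098). The filter did not require reads in every line. Gm13272, mmu-mir-465c-1 and mmu-mir-7221, for example, had a log2 ratio of 0 in the Trim28 line. The correlations therefore mix genes with and without reads in a line, and do not show that the lines disagree. The means of 100 shuffles of guides among genes were 0.135, 0.133 and 0.167, with ranges of −0.107 to 0.379, −0.126 to 0.381 and −0.111 to 0.401. Genes are not independent replicates, so no p is given for these 3 correlations.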

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

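The test for a difference between lines and the look at non-targeting reads below were chosen after the counts had been seen. Retention of guides of the naive exit list in unsorted cells differed between lines in a permutation test (p = 0.000600, adjusted over 29 lists 0.0174). The gap to guides of like plasmid count was 21.5 percentage points in the Trim28, 7.83 in the Dnmt3L and 3.5 in the Nanog line, above 0 in 3 of 3. The cause was not tested.

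Non-targeting guides, which the gene comparisons leave out, held 6.44% of the reads of the sorted Trim28 library, against 1.43% in the plasmid pool, 2.76% in the unsorted Trim28 library and 0.299% and 0.212% in the sorted Nanog and Dnmt3L libraries. A single guide (CCGTTTCGCCTATTGGTGCG) accounted for 5.85% (95% Wilson interval 5.84 to 5.86), with 823926 reads after sorting, 134138 before and 225 in the plasmid pool.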

How the results depend on the processing

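For sorted against unsorted cells, 0 guides were called in the paired edgeR fit, 73 without the line as a block and 623 by DESeq2. For genes the count was 0, and it ran from 0 to 1 with a line left out (1 without the Nanog line). With a plasmid minimum of 30 most tested guides had no read in any of the 6 libraries, and that fit is not reliable. Among lists, none called, the direction reversed with fry for TGF-beta, NODAL and BMP (adjusted p = 0.754), DNA methylation and TRIM28 silencing (0.458) and biliverdin and haem (0.86). It reversed with the size factors of DESeq2 for vomeronasal receptors (0.942), FGF-RAS-ERK activators (0.942), mTOR activators (0.916) and pluripotency factors (0.916), with total counts for TGF-beta, NODAL and BMP (0.821), with scaling on non-targeting guides for mTOR activators (0.978) and pluripotency factors (0.978), and without a block for pluripotency factors (0.975). With a line left out, the adjusted p of the vomeronasal, FGF-RAS-ERK activator, mTOR activator, pluripotency, pausing and elongation, acetyltransferase and COMPASS, and laminin lists ran from 0.813 to 0.999, and that of TGF-beta, NODAL and BMP from 0.795 to 0.999. Each changed direction at least once.

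Among named genes, the log2 ratio of mmu-mir-182 was −0.50 with no filter and −0.50 with a plasmid minimum of 30, and that of mmu-let-7f-2 was 0.30 with both and 0.62 on summed counts. Olfr996 was 1.03 with the size factors of DESeq2 and 0.16 on summed counts, and Pfkl was −1.61 with total counts. Within lines, the number of genes up in the Dnmt3L line was 15 with total counts, against 35, and in the Trim28 line 112 with no filter, against 16.

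For unsorted cells against the pool, the 5365 genes became 3072 at a plasmid minimum of 100 and 0 on summed counts, and from 0 to 9107 with a line left out (9107 without the Nanog line, 0 without either other line). The 8 lists became 0 with an estimated correlation, 28 with fry, all lower, and 4 with any line left out (range 4 to 4). The fry direction, lower, was the reverse of camera for the p53 pathway (adjusted p = 0.0408), olfactory receptors (0.0194), FGF-RAS-ERK activators (0.0173), JNK and p38 (0.0194), mTOR activators (0.0194), mTOR antagonists (0.0249), naive exit (0.0194), Polycomb (0.0194) and biliverdin and haem (0.0511), because fry asks whether a list fell at all and camera whether it fell more than other guides. With a line left out the adjusted p ran from 0.614 to 0.987 for WNT activators, from 0.635 to 0.911 for acetyltransferases and COMPASS, and from 0.46 to 0.938 for laminin adhesion, with a change of direction in each.

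The log2 ratio of Asxl2 was 0.66 with the size factors of DESeq2 and 0.86 on summed counts. That of Vmn2r85 was 0.79 at a plasmid minimum of 100 and 0.80 on summed counts, where Furin was 0.21 and Trim28 0.48. Dnmt3l was −0.41 with total counts, and from −3.32 to 1.92 with a line left out. The same range was −0.16 to 5.93 for Hk2, −0.78 to 5.21 for Lamtor2, and −1.05 to 2.73 for Frs2. The lowest value came without the Dnmt3L line for Frs2 and without the Nanog line for the others. The cause was not tested.

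The 8 expanded genes became 7 at 30 CPM and 7 at 300 CPM (without Rraga), 5 at a carry-over limit of 0.02 and from 5 to 6 with a line left out, where Trp53, Lamtor1 and Ptpn2 were called each time. Among the 10 retention lists the direction never changed. With a minimum of 1 read or of 30 reads in place of 10, 11 lists passed, with PI3K-AKT-mTOR antagonists added as higher. At 10 reads their guides were found in 23.3% of cases against 17.3% by chance (randomization test, adjusted p = 0.215). The settings on technical replicates of the sorted libraries were not run, because the table has 1 sorted column per line.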

Other observations

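Of the tests in this part, those of GC content and of other splits of the libraries were set before their results were seen; the tests of carried-over reads, plasmid DNA, plasmid abundance, lines left out and olfactory receptor guides were chosen afterwards. The genes in this paragraph were also chosen after their counts were seen. Nmt1, which encodes an enzyme that attaches myristate to proteins, was led by different guides in different sorted populations: GAACTGGTAGCTCCGTTTAC had 639371 reads in the sorted Nanog line, against 384 unsorted, and GTAAACGGAGCTACCAGTTC had 786824 reads in the sorted Dnmt3L line, against 106116 unsorted. Nmt1 was called expanded in unsorted cells when no limit on carried-over reads was set, but not otherwise. Hmox2 encodes a haem oxygenase, an enzyme that makes biliverdin. Its guide GAATCCGATCCACATACTTC had 201 reads in unsorted and 204732 in sorted cells of the Nanog line, 23 and 34361 in the Trim28 line, and 36 and 37 in the Dnmt3L line. The other Hmox2 guides had 0 reads in every cell library, so the gain rests on 1 guide in 2 of 3 lines (exact randomization p = 0.00104, adjusted p = 1 over all genes).

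Guides with at least 50000 reads in 1 library had reads in libraries of other lines 6.66 times as often as guides of like plasmid count (median of 24 pairs, range 3.06 to 9.58), at a median of 40.5 to 786 ppm of the source count. This is consistent with reads carried over between libraries, for example by misassigned index reads. Plasmid DNA in the cell libraries was not settled, since the share of the plasmid's most abundant guides (the top stratum of 10) with 0 reads was as low as 48.6% in 1 unsorted library, close to the bound of 50% set for it.

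The expansion of 8 genes in unsorted cells was examined for clones that grew out whatever their guide and for carried-over reads. Genes called on a pair of lines had 26 expanded guides of 51 in the line left out, summed over the 3 choices (10 of 18 in the Nanog, 6 of 18 in the Trim28 and 10 of 15 in the Dnmt3L line), against 0.445 expected and at most 5 in 10000 random sets of like plasmid count, which argues against chance growth alone. The 3 choices were not independent, since Trp53, Lamtor1 and Ptpn2 were called in each, so their guides enter the 51 more than once. Each choice taken alone was also above its highest random number (2, 3 and 4). Of the 26, 10 (2, 3 and 5) had more reads than in any library of another line. The random sets counted expanded guides whether or not this held for them, so they are only a loose reference for the 10. The highest random numbers were 2, 3 and 4 in the Nanog, Trim28 and Dnmt3L lines and 5 over all lines. The rest of the 26 had at least as many reads in a library of another line, so carried-over reads are not excluded for them. Expanded guides above every library of another line were found in at least 2 lines for 5 of the 8 genes (Trp53, Lamtor1, Fnip1, Lamtor4 and Flcn). For Ptpn2, Fbxw7 and Rraga they were found in 1 line. At the limit of 0.02, Fbxw7, Lamtor4 and Rraga missed the adjusted threshold, and the other 5 stayed called.

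Non-targeting guides were retained more often than guides against genes. The gap was 4.35 ± 1.33 percentage points within 10 strata of plasmid count, 4.16 ± 1.37 when matched on GC content as well, and 4.39 ± 1.04 against olfactory receptor guides alone (SD, n = 3 lines, higher in 3 of 3; permutation p = 2e-05 for each, the smallest that 100000 permutations can give). Neither plasmid abundance, nor GC content (55.3% in non-targeting and 53.2% in other guides), nor loss of essential genes accounts for it. A cost of DNA cutting itself in these cells may contribute, as a hypothesis that no sample here separates from other differences between the guides.

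For sorted against unsorted cells, all 10 of the 10 splits of the 6 libraries into groups of 3 gave as many called genes, and 10 as many called guides, as the real split, whose edgeR counts were 0 with a highest other count of 0. With 10 splits no share under 0.05 can arise. DESeq2 called 623 guides in the real split and between 5 and 203 in the others; among the 4 splits that part all lines the highest other count was 61.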
